A study of Mus musculus with 2 samples.

How the data were processed

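Total RNA from mouse lung was extracted with Trizol, labelled with biotin from 300 ng and hybridised to Affymetrix gene-level whole-transcript arrays, per the labels' protocols. The series holds 2 samples, 1 array of nonirradiated and 1 array of irradiated lung, and the labels assign each to its group. The exact array type is not given in the sources used here.

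The deposited values are RMA values on the log2 scale, made by the authors with RMA in Affymetrix Expression Console 1.3.1, per the submitters' processing notes. As usually run, RMA subtracts a background, forces the arrays onto a common distribution (quantile normalisation) and summarises the probes of each transcript cluster, the array's unit of about 1 gene. It therefore centres the arrays on each other, so a shift shared by most genes cannot be seen, and it compresses the differences of dim transcripts. A workbook of the authors repeats the same values, which differed from the value table by less than rounding error, and adds a log2 ratio and an absolute fold change. The deposited log2 ratio equalled the irradiated minus the nonirradiated value in every row, and the authors' fold, a ratio of at least 1, is its antilog regardless of direction. Sheets deposited by the authors list 1592 rows at 1.5-fold (1085 higher and 507 lower in the irradiated array) and 292 rows at 2-fold (219 and 73), and in the authors' deposited table these are exactly the rows of the main probe category past each limit. Coordinates refer to GRCm38, the build cited in the deposited annotation.

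The value table has 41345 rows, of which 6980 are array controls (spikes, background probes, ribosomal RNA, and exons and introns of normalisation genes). Counts were made over the other 34365. Of these, 20339 carry 1 gene symbol, 80 carry several and 13946 none. Differences are irradiated minus nonirradiated on the log2 scale, and folds are the larger over the smaller value. The rows of each symbol were averaged, giving 19122 genes. A gene was called bright when the larger of its 2 values reached the median of its array (7.27 nonirradiated, 7.26 irradiated), which left 9846 genes. No detection call was used, so differences from a dim value are given as measured and not as bounds.

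Before the data were examined, 40 gene lists and 3 gene families (immunoglobulin segments, ribosomal proteins, mitochondrial transcripts) were fixed from general knowledge of lung tissue, fibrosis, radiation injury and of neighbouring tissues. Of 864 list entries, 722 matched a symbol as written, 6 matched through a RefSeq synonym and 136 were not matched, in part because their transcript clusters carry no symbol. A list was described when at least 5 members were bright. Its median difference was given as a percentile among 10000 random lists of the same size drawn from the same 20 bins of mean log2 value, and it stood apart at or beyond the 2.5th or 97.5th percentile. Mast cells and eosinophils (2 bright members), thymus (4) and mitochondrial transcripts (0 symbols) were not described. Genes in the text were named by a rule fixed at the same time: the 12 bright genes with the largest difference in each direction, leaving out predicted genes, symbols that begin with Mir, snoRNA, olfactory and vomeronasal receptor and immunoglobulin segment symbols, up to 4 members with the largest absolute difference from each described list, and Acta2. The microRNA precursor mmu-mir-297a-2 does not begin with Mir and was kept. No single immunoglobulin segment was named. Some genes that the rule names are not reported here. Among the genes the report names, Actn1, Col1a1, Myh7, Hba-a2, Hbb-bt, Il1b, Usp18, Ifit1, Sftpc, Scgb1a1 and Cdkn1a fall outside this rule and were chosen after their values were seen. The closing section names further genes outside this rule, among them Actc1, Myh6, Tnnt2, Prtn3 and Lcn2, and these too were chosen after the named genes had been seen.

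No p-value was computed, since each group has 1 array and genes are not replicates. Technical spread was described from 18 bacterial hybridisation control rows, whose differences had an SD of 0.14, from 39 poly-A spike rows (0.31), 92 ERCC rows (0.24) and 23 antigenomic background rows (0.21), and from 963 rows of 407 bright genes with several rows, whose differences had a pooled SD of 0.28 within genes. The list percentile was tested on simulated data: with trend-corrected differences shuffled over 9846 genes, 4.50% of lists of 10 and 7.50% of lists of 20 stood apart without any shift, and an added log2 shift of 0.2 was called in 70.5% of lists of 10 and 95.0% of lists of 20. At a shift of 0.4 all simulated lists were called. The shuffling removed any correlation between genes. These rates therefore do not hold for lists whose members vary together, such as markers of 1 cell type.

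Alternatives fixed in advance were median centring, removal of a lowess trend on mean log2 value (span 0.3), other brightness limits (none, the array median for rows, the 75th percentile), 1 value per gene, the brightest row of each gene, the workbook's values, unmatched random lists, lists without shared genes, the mean in place of the median, and lists without the member that differed most. Alternatives chosen after seeing the data were the main probe category alone, removal of rows annotated with cross-hybridisation type 3, rows with at least 20 probes, and naming of rows without a symbol by position. In the last, a row took the name of the only protein-coding gene in RefSeq's GRCm38.p6 table with at least 90% reciprocal overlap, regardless of strand, which the table lacks. Among 14037 rows that had a symbol and a match, 97.2% matched the same gene, and 3346 rows without a symbol were named in this way. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.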

Results

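Gene expression was measured in the lungs of male C57BL/6 mice whose chest had been irradiated with gamma rays at 7 weeks of age, and in lungs of nonirradiated mice. C57BL/6 is an inbred laboratory strain that develops lung fibrosis, a build-up of scar tissue, months after chest irradiation. Lungs were collected after 25 weeks, and fibrosis had been assessed in the study by tissue staining and by a western blot for alpha-smooth muscle actin, a contractile protein of smooth muscle cells and myofibroblasts. The dose rate was 0.81 Gy/min, and the total dose is not given in the sources used here. Each group was measured on 1 gene-level expression array, labelled from 300 ng of total RNA. How many mice contributed to each array is not given in the sources used here. The deposited RMA values were on a log2 scale and ran from 1.69 to 13.83 in the nonirradiated array and from 1.51 to 13.78 in the irradiated array. With 1 array per group there is no replicate error and no test, so every value below describes these 2 arrays, and their number limits the precision.

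The comparison asked which transcripts differed between irradiated, fibrotic lung and nonirradiated lung. Genes of fat cells, heart muscle and smooth muscle were higher in the irradiated array, as were immunoglobulin segments and genes of blood cells, T cells and NK cells. Genes of the lung epithelium, the mesothelium that covers the lung, the basement membrane and sterol synthesis were lower. Among bright genes with a symbol, the largest difference was in Ucp1, the heat-producing mitochondrial carrier of brown fat, which was higher by 3.33 on the log2 scale in the irradiated array, from a value below the array median in the nonirradiated one. The largest lower value among the named genes was that of Clca3, a secreted protein of mucus-producing goblet cells, which was 4.16-fold lower. Fibrillar collagen genes differed little.

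Of 34365 transcript clusters that were not array controls, 1657 differed at least 1.5-fold between the arrays, 1130 of them higher and 527 lower in the irradiated array. At 2-fold, 242 were higher and 85 lower. Transcript clusters without a gene symbol made up 916 of the 1657, and 72.6% of these were higher in the irradiated array, against 62.5% of the 720 clusters with 1 symbol. Clusters with few probes were over-represented: the 1657 had a median of 13 probes, against 22 among all non-control clusters. When values were averaged per gene and restricted to the 9846 genes that were bright in at least 1 array, 175 genes were at least 1.5-fold higher and 100 lower in the irradiated array. At 2-fold these numbers were 43 and 7. A gene could enter by its value in 1 array alone, and where the other value was dim the size of the difference is uncertain. Such a gene could differ only toward the array that let it in. Among others, Ucp1, Ngp, Cidea, Lep, Ttn, Casq2, mmu-mir-297a-2, Tnc, Ccl7, Ckm and Krt15 could only be higher. Clca3, Gp2, Muc16, Muc5ac, Has1, S100a9 and Nqo1 could only be lower.

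**Figure D1:**
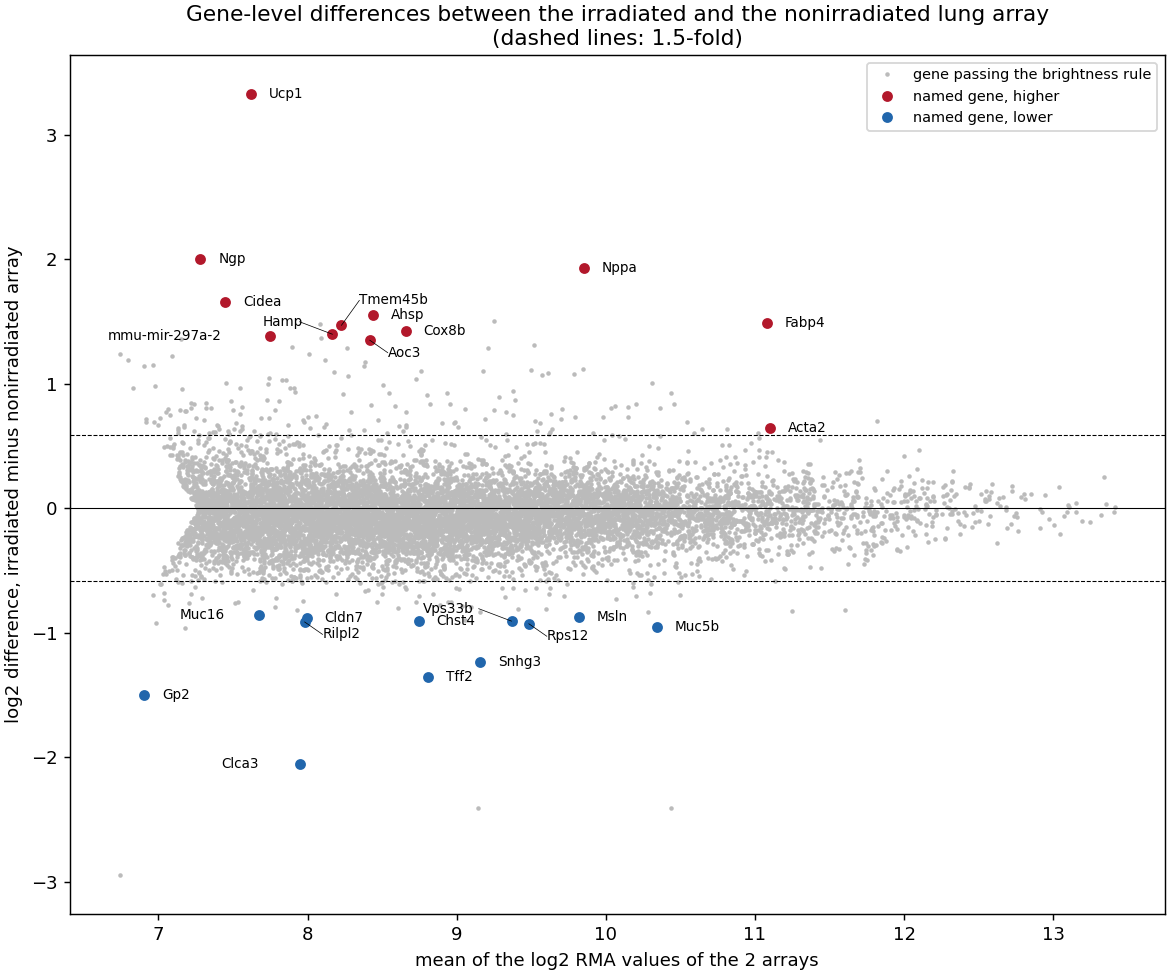
Log2 difference, irradiated minus nonirradiated array, against the mean log2 RMA value of the 2 arrays, 1 point for each of 9846 bright genes. Red and blue points are genes named in the text as having the largest differences in each direction and Acta2, and dashed lines mark 1.5-fold; Ucp1 lies highest at 3.33, and the unlabelled points below Clca3 at -2.06 are predicted genes, a class that the naming rule left out.

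Acta2 encodes alpha-smooth muscle actin itself. Its transcript cluster 17364098 on chromosome 19 (34241090 to 34255336, minus strand, GRCm38) read 10.78 in the nonirradiated and 11.42 in the irradiated array, a 1.57-fold higher value. The irradiated mice were described as overexpressing this protein, so neither Acta2 nor the contractile list that holds it is independent evidence of its direction. Among 17 contractile genes of smooth muscle and myofibroblasts, 16 were higher in the irradiated array and 6 were at least 1.5-fold higher. The median log2 difference of 0.43 lay above all 10000 random lists of the same size matched on mean expression. Cnn1, the smooth muscle calponin, was 2.48-fold higher, Actg2, the gamma actin of smooth muscle, 1.78-fold, and Myh11, the smooth muscle myosin heavy chain, 1.62-fold. Hhip, an inhibitor of hedgehog signalling, was 1.59-fold higher, whereas Actn1, a non-muscle actinin, differed by -0.09. Heart muscle and adipocyte genes were higher in the same array, with list medians of 0.74 and 0.91.

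The matrix gene groups did not share a direction. Fibrillar collagens and their processing enzymes had a median log2 difference of 0.09 over 17 genes, at percentile 99.1 of random lists, but 9 genes were higher, 8 were lower and none reached 1.5-fold. Col1a1, a chain of the main fibrillar collagen, differed by 0.13, the collagen cross-linking enzyme Lox by 0.38 and its relative Loxl3 by 0.34, whereas the prolyl hydroxylase P4ha2 differed by -0.37. With the mean in place of the median this list lay at percentile 89.8, and without clusters annotated as cross-hybridising at 62.1. Among 16 matrix glycoproteins and proteoglycans, 14 were higher, with a median of 0.15 at percentile 99.8. Thbs1, thrombospondin 1, was 1.43-fold higher and Tnc, tenascin C, 1.31-fold higher, while Has1, a hyaluronan synthase, was 1.72-fold lower. The brightness rule fixed the direction of Tnc, dim in the nonirradiated array (7.21), and of Has1, dim in the irradiated array (6.67). Basement membrane genes were lower in 13 of 17 cases, with a median of -0.35 that lay below all random lists. The laminin chains Lamb3 and Lama3 differed by -0.64 and -0.58, and the collagen IV chain Col4a4 by -0.43.

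Several other groups tied to fibrosis lay within the central 95% of random lists. The 20 genes of the TGF-beta pathway, the signalling system that drives myofibroblast formation, had a median of -0.03 at percentile 56.2. Tgfb2 differed by -0.37, and the target Ctgf by 0.27. The 15 matrix proteases and inhibitors had a median of -0.06 at percentile 45.3, with Adam8 1.51-fold lower, or -0.52 on the log2 scale with the intensity trend removed. The 6 genes of mesenchymal transition had a median of 0.14 at percentile 97.2, and with rows named by position added the list lay past the limit at 98.7. The 22 genes of fibroblasts and pericytes had a median of 0.04 at percentile 94.8. The pericyte genes Rgs5 and Higd1b in it were 1.74-fold and 1.56-fold higher, from dim values of 6.66 and 6.81 in the nonirradiated array. Both entered only through the irradiated array and so could only be higher, whereas the bright Notch3 of the same list differed by -0.28.

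Adipocyte genes formed the group with the highest median. All 13 were higher in the irradiated array and 12 were at least 1.5-fold higher, with a median log2 difference of 0.91 above all random lists. Ucp1 (chromosome 8, 83290348 to 83298456, plus strand, GRCm38) read 5.96 in the nonirradiated array, below the median of 6.33 of intron control rows there, and 9.29 in the irradiated array. Cidea, a lipid droplet protein of brown fat, was 3.15-fold higher, Fabp4, a fatty acid carrier of adipocytes, 2.80-fold, and Lep, the adipocyte hormone leptin, 2.45-fold. Of the 13 genes, 8 were above the array median in the nonirradiated lung. The others, among them Ucp1, Cidea (6.62) and Lep (7.25), entered only through the irradiated array and so could only be higher. Elovl3, a further member of this list, was dim in both arrays, was left out by the brightness rule and differed by -0.11. Cox8b, a cytochrome oxidase subunit of brown fat and heart, was 2.68-fold higher, and Aoc3, an amine oxidase of adipocytes and smooth muscle, 2.55-fold higher.

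Heart muscle genes were higher in 16 of 17 cases, and 14 were at least 1.5-fold higher. The list median of 0.74 lay above all random lists. Nppa (chromosome 4, 148000722 to 148002079, plus strand, GRCm38), the atrial natriuretic peptide, was 3.81-fold higher. Pln, which regulates the calcium pump of heart muscle, was 2.15-fold higher, Ttn, titin, 2.07-fold, and Casq2, the cardiac calsequestrin, 1.94-fold. Myh7 was the exception at -0.18. Of the 17 genes, 14 were above the array median in the nonirradiated lung. The others, among them Ttn (7.22) and Casq2 (6.68), entered only through the irradiated array and so could only be higher. The 5 bright skeletal muscle genes had a median of 0.22 at percentile 97.7, with Ckm 1.53-fold higher, but all 17 skeletal muscle genes with a symbol, dim ones included, had a median of 0.05 at percentile 81.8.

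Genes of red blood cells and platelets had a median log2 difference of 0.47 over 12 genes, above all random lists, and 5 were at least 1.5-fold higher. Ahsp, the chaperone of alpha haemoglobin, was 2.93-fold higher, and the platelet chemokine Ppbp 1.63-fold. The globin genes Hba-a2 and Hbb-bt differed by 0.09 and -0.22. Ngp, a granule protein of immature neutrophils, was 4.01-fold higher, from a dim value of 6.28 in the nonirradiated array. It belonged to a neutrophil list of 12 genes whose median was -0.09, at percentile 32.0, and whose mean was 0.06. In that list S100a8 and S100a9, abundant proteins of mature neutrophils, were 1.45-fold and 1.42-fold lower. Ngp entered only through the irradiated array and could only be higher. S100a9, at 7.23 in the irradiated array, entered only through the nonirradiated one and could only be lower. Other genes among the 12 largest higher values were Hamp, the iron hormone hepcidin, at 2.64-fold, Tmem45b at 2.77-fold and the microRNA precursor mmu-mir-297a-2 at 2.61-fold, of which Hamp and mmu-mir-297a-2 rest on clusters of 10 probes annotated as cross-hybridising.

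Immunoglobulin segments were higher in all 18 cases, 12 of them at least 1.5-fold, with a median of 0.75 above all random lists. These segments are closely related in sequence and their probes can share signal, so they are described as a family. Among 10 plasma cell genes the median of 0.10 lay at percentile 97.1, and Igj, the joining chain of secreted antibodies, was 1.55-fold higher. B cell genes had a median of 0.15 over 12 genes at percentile 99.9, none at 1.5-fold, with Cd79a at 0.29. The 20 genes of T and NK cells had a median of 0.21, above all random lists. Icos, a co-stimulatory receptor of T cells, was 1.52-fold higher and Prf1, the pore protein of cytotoxic cells, 1.39-fold. Among the brightest genes alone this list lay at percentile 96.6.

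Cytokines and chemokines had a median of 0.18 over 20 genes, above all random lists, and 4 were at least 1.5-fold higher. Cxcl9, a chemokine induced by interferon gamma, was 2.26-fold, Cxcl13, which attracts B cells, 1.79-fold and Ccl7 1.58-fold higher, while Il1a differed by 0.59 and Il1b by -0.49. When only the brightest genes were kept, this list lay at percentile 84.0. The 23 interferon-stimulated genes had a median of 0.15, above all random lists, with 16 higher. The GTPases Igtp and Iigp1 were 1.86-fold and 1.72-fold higher, and Usp18 and Ifit1 differed by -0.27 and -0.26. MHC class II genes had a median of 0.11 over 6 genes at percentile 95.6, with Ciita, their transcriptional activator, at 0.24. Complement genes had a median of -0.16 over 15 genes at percentile 3.69, with C2 1.62-fold lower and Cfd, which adipocytes secrete, 1.59-fold higher.

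Macrophage lists were lower. Alveolar macrophage genes had a median of -0.22 over 18 genes, at percentile 0.12, and Chi3l3, a chitinase-like secreted protein, was 1.46-fold lower. Of the 18 genes, 5 also stood in other lists, among them Cidec, which was 1.61-fold higher and is an adipocyte gene as well. Interstitial and monocyte-derived macrophage genes had a median of -0.21 over 17 genes, at percentile 0.915. Retnla, a marker of alternatively activated macrophages, was 1.61-fold lower, and Ly6c2, of inflammatory monocytes and annotated as cross-hybridising, 1.38-fold higher. Without genes shared with other lists the interstitial list lay at percentile 28.1, and with the mean in place of the median the alveolar list lay at percentile 5.04.

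Every epithelial list lay below the central 95% of random lists. Ciliated cell genes were lower in 24 of 24 cases, with a median of -0.34 below all random lists. Rsph4a, a radial spoke protein of cilia, was 1.75-fold lower, and Foxj1, the transcription factor that directs cilium formation, 1.46-fold lower. Alveolar type 1 cell genes were lower in 13 of 14 cases, with a median of -0.27 below all random lists, and Pdpn, podoplanin, differed by -0.49. Alveolar type 2 cell genes were lower in 17 of 19 cases, with a median of -0.22 at percentile 0.01. Sftpd, surfactant protein D, was 1.36-fold lower, whereas Sftpc, near the top of the signal range, differed by -0.03. Club and goblet cell genes had a median of -0.19 over 18 genes, at percentile 0.2, and 4 were at least 1.5-fold lower, among them the airway mucins Muc5b at 1.93-fold and Muc5ac at 1.60-fold. Muc5ac, dim in the irradiated array (6.70), entered only through the nonirradiated array and so could only be lower. Scgb1a1, the main secretory protein of club cells and likewise near the top of the signal range, where a change can be hidden, differed by 0.01. Basal and transitional epithelium had a median of -0.21 over 10 genes at percentile 2.03, with the tight junction protein Cldn4 1.68-fold lower and the keratin Krt15 1.41-fold higher, and lay at percentile 31.6 without Cldn4.

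Mesothelial genes were lower in 10 of 10 cases, with the lowest median of any list, -0.48, below all random lists. Msln, mesothelin, was 1.83-fold lower, Muc16, a mucin of mesothelial surfaces, 1.82-fold and Bnc1, a transcription factor, 1.61-fold. Other genes were among the 12 largest lower values. Clca3 (chromosome 3, 145004537 to 145032776, minus strand, GRCm38) read 8.98 in the nonirradiated and 6.92 in the irradiated array. Gp2, a membrane glycoprotein of secretory granules, was 2.84-fold lower, Tff2, a trefoil factor secreted with mucus, 2.57-fold, Chst4, a sulfotransferase that modifies mucin-type glycans, 1.88-fold and Cldn7, a claudin of epithelial junctions, 1.85-fold. The remaining lower genes were Snhg3, a host gene of small nucleolar RNAs, at 2.36-fold, Rilpl2 and Vps33b, both at 1.88-fold, and Rps12 at 1.90-fold, with Snhg3 and Rps12 annotated as cross-hybridising.

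**Figure D2:**
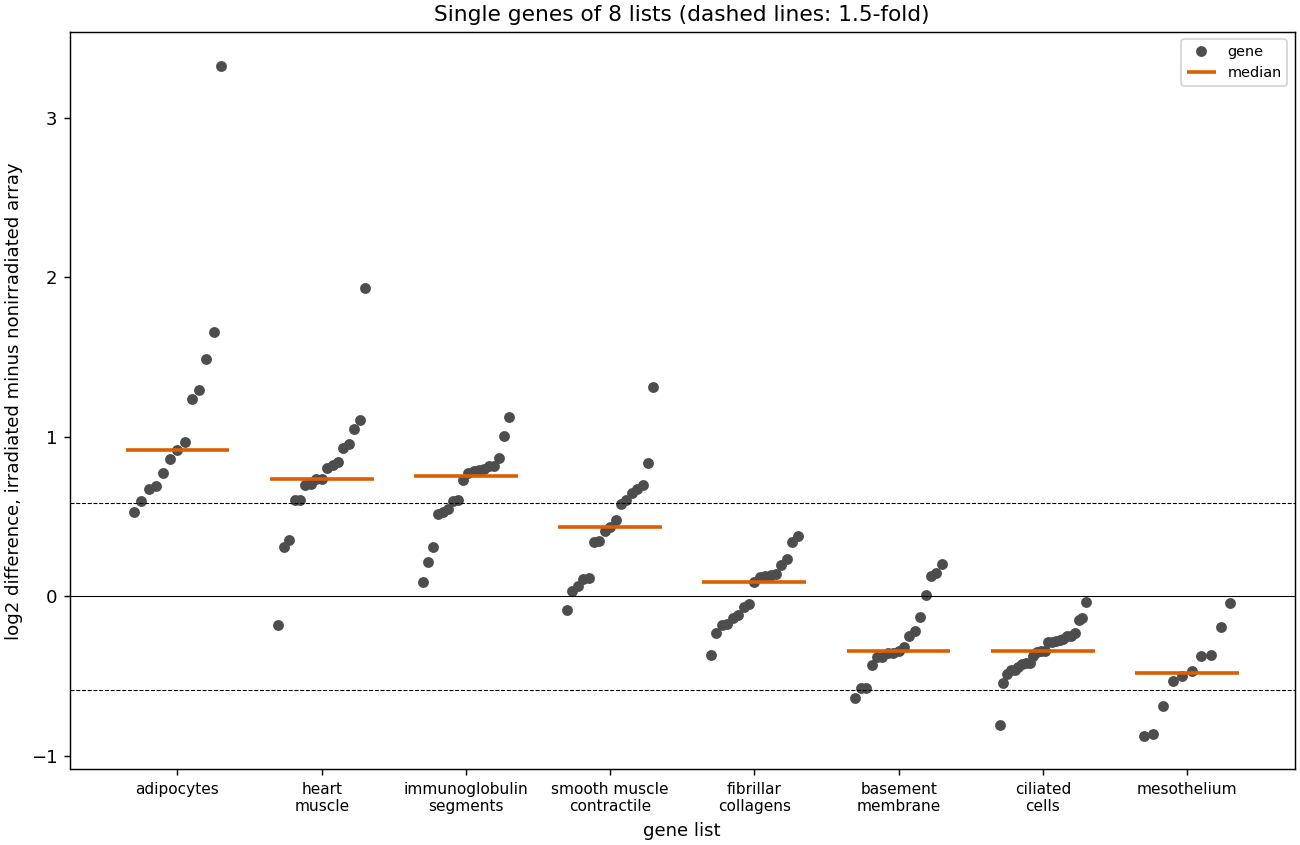
Log2 difference, irradiated minus nonirradiated array, of each bright gene in 8 lists, sorted within a list; orange bars are list medians and dashed lines mark 1.5-fold. All 13 adipocyte genes, 8 of them above the array median in nonirradiated lung, lie above 0. All 24 ciliated cell and 10 mesothelial genes lie below 0, while 9 of 17 fibrillar collagen genes lie above it.

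Endothelial genes were slightly higher. The 24 genes of vascular endothelium had a median of 0.13, above all random lists, but none reached 1.5-fold, and Apln, the vascular peptide apelin, was 1.46-fold higher. The 7 genes of lymphatic endothelium had a median of 0.11 at percentile 96.0, with Mmrn1 1.36-fold higher and Pdpn, shared with the type 1 cell list, 1.40-fold lower.

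Among metabolic and stress programmes, the largest list shifts were downward. Sterol and fatty acid synthesis genes were lower in 20 of 21 cases, with a median of -0.22 at percentile 0.02. Hmgcs1, an early enzyme of cholesterol synthesis, was 1.55-fold lower, Fdps 1.45-fold and Lss 1.41-fold. Antioxidant genes, only some of them under the control of NRF2, had a median of -0.21 over 20 genes at percentile 0.06. The glutathione transferase Gsta4 was 1.42-fold and the quinone reductase Nqo1 1.33-fold lower. Cell cycle genes had a median of 0.15 over 17 genes at percentile 99.8, with Ccna2, cyclin A2, 1.31-fold higher. Tyms, thymidylate synthase, averaged 1.58-fold higher, but its 2 transcript clusters differed by -0.0445 and 1.36. Immediate early and heat shock genes had a median of 0.11 over 20 genes at percentile 99.9, with the inducible heat shock protein gene Hspa1b 2.15-fold higher and Ier3 at -0.38.

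Targets of p53, the transcription factor of the DNA damage response, had a median of -0.13 over 15 genes at percentile 7.83. Cdkn1a, its cell cycle inhibitor target, differed by 0.14 and Bax, a mediator of cell death, by -0.28. This list lay at percentile 2.02 when dim genes were included. The 9 senescence-associated genes had a median of -0.03 at percentile 52.2, the 15 circadian clock genes -0.04 at percentile 52.6 and the 16 genes of the unfolded protein response -0.07 at percentile 26.3. Ribosomal protein genes were lower in 39 of 49 cases, with a median of -0.14 at percentile 0.465. The 10 transcript clusters of Rps12 differed by between -1.01 and -0.70, and Rps28 was 1.77-fold lower. Part of the ribosomal protein clusters are annotated as cross-hybridising, and without such clusters the list lay at percentile 21.9.

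**Figure D3:**
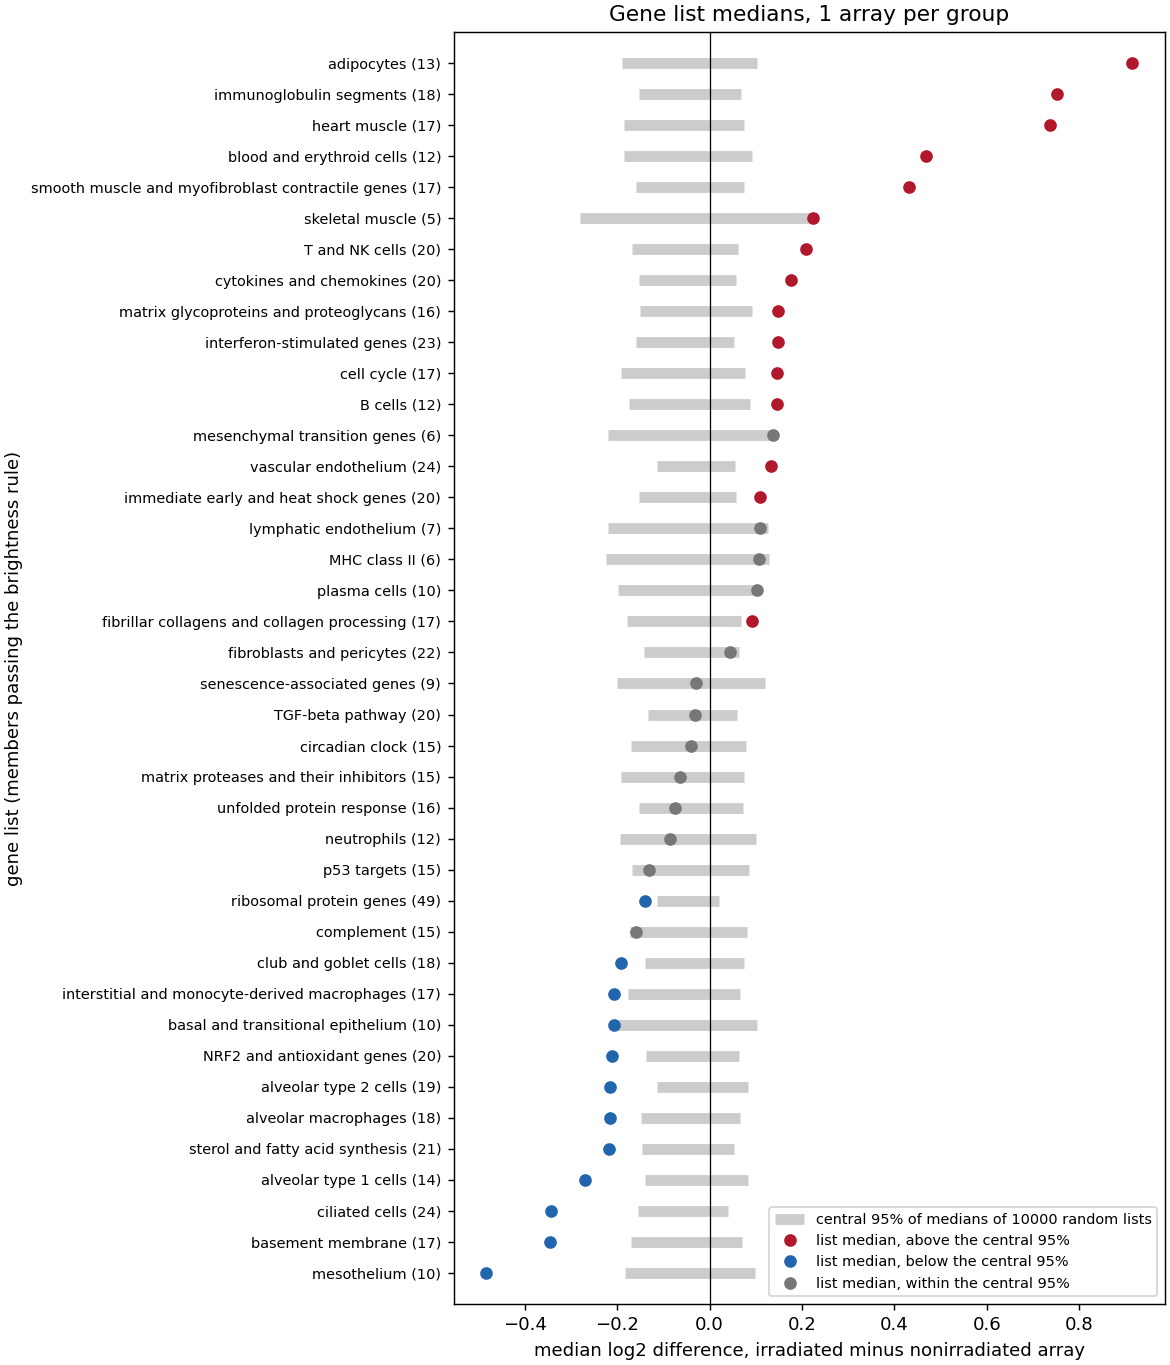
Median log2 difference, irradiated minus nonirradiated array, of each of 40 described gene lists and families, with the number of bright genes in parentheses; grey bars span the central 95% of medians of 10000 random lists of the same size matched on mean expression. The medians run from -0.48 for mesothelium to 0.91 for adipocytes; 15 lie above and 12 below the grey bars.

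Because each group is 1 array, a difference between the conditions and a difference between the lung pieces taken cannot be separated in any of these values. A list that stands outside the random lists describes these 2 arrays only.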

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

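All tests in this part were chosen after the pattern they address was seen. The second adipocyte, second heart, further smooth muscle and activated fibroblast lists and the receptor rows had their limits written down before their own values were looked at, while the comparison with endothelium, the number of arrays, the brightness gradient of the intron rows and the exon rows of few probes were set after. The demand that a list miss its limit by more than its bootstrap interval was also added after the percentiles were known, and it was asked only of lists below their limit. The second adipocyte, second heart and activated fibroblast lists passed on their medians alone, and their intervals include the upper random bounds of 0.09, 0.14 and 0.11. For the intron rows, an earlier test on the median of all exon rows and one on brightness alone were replaced after their values were known.

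Array controls outside the comparison also differed. The 5331 intron rows of normalisation genes had a median log2 difference of 0.27, and 71.1% were higher in the irradiated array, which singled them out as a control class higher by more than 0.1. The 25 ribosomal RNA rows had a median of 0.10 and were singled out for the same reason. For comparison, 1352 exon rows of the same control class had a median of -0.08 and 92 ERCC spike rows -0.07. Other control classes were lower by more than the ribosomal RNA rows were higher, with -0.16 in 39 poly-A spike rows and -0.21 in 23 antigenomic background rows.

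For the intron rows, genomic DNA carried into the irradiated sample would raise genes that lung does not transcribe, but 1453 rows of olfactory and vomeronasal receptors had a median difference of 0.0354 (95% bootstrap interval 0.00 to 0.05). That value was set against 0, while the 23 antigenomic background rows differed by -0.21. Against that background the receptor rows were higher, so the test cannot set genomic DNA aside. Few probes or dimness would raise exon rows alike, but exon rows of at most 5 probes at the same brightness had a median of -0.0927 (-0.14 to -0.02). Unspliced RNA may account for the pattern and stays open, since the brightest intron rows exceeded the dimmest by 0.0508 with an interval of -0.00 to 0.10, and the dimmest were themselves higher by 0.27. No biological explanation was tested for these rows.

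The higher adipocyte and heart muscle genes could reflect more fat and heart muscle in the piece of irradiated lung, since fat lies beside the hilum and mouse pulmonary veins carry heart muscle. A second adipocyte list of 15 bright genes, 12 of them above the array median in nonirradiated lung, had a median of 0.28 (-0.03 to 0.39). It lay at percentile 100 with 9 above 0, Tusc5 at 0.84 and Slc2a4 at 0.81, but Cebpa at -0.46. The genes below that array median, Slc2a4 (6.91), Pnpla3 (6.92) and Mlxipl (7.23), entered only through a higher irradiated value. The percentile therefore rests in part on the brightness rule, and no median without these genes was computed. A second heart list of 10 genes, 7 of them above the array median in nonirradiated lung, had a median of 0.21 (0.01 to 0.39). It lay at percentile 99.6 with 8 above 0. Srl (6.82), Cmya5 (7.10) and Apobec2 (7.21) entered it only through a higher irradiated value. Of abundant heart transcripts, Actc1 differed by 0.84, Myh6 by 0.93 and Tnnt2 by 0.61. These stood in the fixed heart list that prompted the test, so they add no new support. Outside that fixed list, Fabp3 differed by -0.27 and the ventricular Myl2, dim in both arrays, by -0.08. The adipocyte median lay 0.78 above that of endothelium (0.53 to 1.24), whereas a smaller share of epithelium would raise all other cells alike. Both medians were known when this comparison was set, and only 8 of the 13 adipocyte genes were above the array median in nonirradiated lung. The comparison therefore restates the pattern and cannot decide on this explanation. A response of lung cells to irradiation cannot be told apart from a difference in sampling, with 1 array per group.

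The higher contractile genes could reflect mature smooth muscle or activated fibroblasts. A list of 8 activated fibroblast genes, all of them above the array median in nonirradiated lung, had a median of 0.11 (-0.03 to 0.23) at percentile 97.8, just past the limit set in advance, with 6 above 0 and Aspn at 0.75. A list of 10 further smooth muscle genes had a median of 0.05 at percentile 88.9, with 5 above 0 and Myocd at 0.64. That lies below percentile 90, set in advance as speaking against more smooth muscle, and counts against it unless the interval of the median (-0.01 to 0.15), which includes the bound of 0.05, is taken into account as was done here. Selection of the irradiated mice for the alpha-smooth muscle actin protein is part of the group and was not tested apart from it.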

How the results depend on the processing

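Values with the main probe category alone, without cross-hybridising rows, with at least 20 probes, or with names by position were chosen after seeing the data. Counts of transcript clusters at 1.5-fold and 2-fold stayed within 1.5 times of 1657 and 327 under centring, trend removal, the workbook's values and the main category alone. Centring and the workbook could not move them, since the median difference of non-control rows was 0 and the workbook repeats the values. The counts fell to 713 and 167 for rows above the array median, 329 and 93 above the 75th percentile, 625 and 79 with 1 value per gene, 1064 and 141 without cross-hybridising rows, and 460 and 55 with at least 20 probes, each of which counts fewer rows. With at least 20 probes the share of rows fell too, from 4.82% to 2.11% at 1.5-fold and from 0.95% to 0.25% at 2-fold. The share higher in the irradiated array was 68.2% of 1657 and 59.6% of 329.

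Over 40 lists, 438 of 471 alternative percentiles stayed on their side of the limits, 26 lists did so throughout, and no list reversed. Of the 471, the 40 with median centring and the 40 with the workbook's values could not change. Centring shifts a list and its random lists alike, and the workbook repeats the same values. The percentiles that changed side follow, and the cause was not tested. With the mean in place of the median, fibrillar collagens lay at 89.8, alveolar macrophages 5.04, interstitial macrophages 7.42, basal epithelium 4.64, complement 1.75 and plasma cells 99.2. Without the most different member, fibrillar collagens lay at 89.9, interstitial macrophages 7.01 and basal epithelium 31.6. Without shared genes, interstitial macrophages lay at 28.1, basal epithelium 49.0 and plasma cells 99.8. Without a brightness filter, p53 targets lay at 2.02, complement 1.59, basal epithelium 28.4 and skeletal muscle 81.8. Above the 75th percentile, cytokines lay at 84.0, complement 0.53, alveolar macrophages 14.7, neutrophils 0.835 and T and NK cells 96.6. With the trend removed, complement lay at 2.19, plasma cells 97.9, lymphatic endothelium 97.6 and skeletal muscle 97.3. With the brightest row, plasma cells lay at 99.9. With names by position, fibrillar collagens lay at 93.1, mesenchymal transition 98.7, interstitial macrophages 23.7 and plasma cells 99.3. Without cross-hybridising rows, fibrillar collagens lay at 62.1, ribosomal proteins 21.9 and plasma cells 99.8.

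Of 668 alternative values of 164 named genes, 660 kept their side of 1.5-fold, 5 fell short of 1.5-fold and 2 passed it. A further 1 turned from a value past 1.5-fold, the lower row of Tyms at -0.0445. Many of the 668 could not differ from the main value. The 164 workbook values repeat it, and the 164 values of the brightest row equal it except in the 6 genes with several rows. A change of sign between values short of 1.5-fold counted as kept, as for Vim, whose lower row was at -0.00719 against an average of 0.15. Acta2 stayed past 1.5-fold in all. Some strict filters left lists under 5 genes, which have no value there. No paired analysis was possible because each group has 1 array. Dim transcripts near the background limit all results, since RMA compresses their differences.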

Other observations

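The test of interferon gamma GTPases against type I genes was chosen after the values were seen; the list of other interferon gamma genes was written down before, but the demand that it miss its limit by more than its bootstrap interval was added after. Genes looked up one by one and names by position were also chosen after seeing the data.

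Genes of the guanylate-binding protein and immunity-related GTPase families, which act against intracellular pathogens, were higher as a family. All 11 bright members lay above 0 and 7 were at least 1.5-fold higher, with a median log2 difference of 0.79. Gbp4 was 2.44-fold, Gbp8 1.99-fold, Irgm2 1.90-fold and Gbp10 1.79-fold higher. In 13 genes typical of type I interferon the median was 0.01, 7 were above 0 and none reached 1.5-fold. The difference of 0.77 between the medians (95% bootstrap interval over genes 0.34 to 1.07) partly restates the split inside the fixed interferon list that prompted it, so it cannot tell whether interferon gamma acted more strongly than type I interferon in the irradiated lung. A wider effect of interferon gamma was not borne out by 14 other interferon gamma genes, which had a median of 0.02 at percentile 84.9 with 7 above 0. That is below percentile 90, set in advance as speaking against it, although the interval of the median (-0.10 to 0.12) includes the bound of 0.03, and Ifng itself was dim in both arrays (6.81 and 6.74). Of the 11 GTPase genes, 4 stood in the fixed interferon list, as did all 13 type I genes.

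Transcript clusters without a symbol could be named by position for part of the list members, a step chosen after seeing the data. Among matrix genes found in this way, Col3a1 differed by 0.04, Fn1 by 0.12 and Eln by 0.14. The secreted phosphoprotein Spp1 was 1.40-fold higher and Fbln5 1.34-fold lower. Pck1, which adipocytes use to make glycerol, was 2.57-fold higher, whereas Lpl, a lipase of the same list, differed by -0.05. Sln, an atrial calcium pump regulator, was 1.65-fold higher, and the mesothelial Upk3b 1.61-fold lower. Tslp was 1.49-fold higher. Of the CD3 chains of T cells, Cd3g was 1.45-fold higher and Cd3e differed by 0.15, whereas Cd3d, which carries a symbol, differed by -0.31.

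Other genes were looked up after Ngp and Ahsp had been seen. The neutrophil granule genes Camp, Elane and Mpo, dim in both arrays, differed by 0.57, 0.41 and 0.41, whereas the bright granule genes Prtn3 and Lcn2 differed by -0.13 and -0.04. The red cell gene Rhag, also dim, differed by 0.89. The brown fat genes Otop1 and Cox7a1, looked up in the same way, were 2.34-fold and 1.71-fold higher, Otop1 from a dim value of 6.48. Elovl3, a member of the fixed adipocyte list that was dim in both arrays, differed by -0.11, and Fabp3, of brown fat and heart, by -0.27. In the lists too short to describe, the mast cell genes Cpa3 and Kit differed by 0.97 and 0.35, and the thymus genes had a mean of 0.11. Of 30 transcript clusters on the mitochondrial chromosome, none with a usable symbol, 27 were higher in the irradiated array, with a median of 0.10.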
